A study of Mus musculus with 4 samples.

How the data were processed

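RNA was measured by sequencing in mouse embryonic fibroblasts of the ICR strain on day 8 of reprogramming. The cells had been infected with retroviruses carrying Sox2, Klf4 and Oct4 (SKO; the gene of Oct4 is Pou5f1) together with either Glis1, a zinc finger transcription factor, or a Flag control. There were 4 libraries, 2 per group, each group holding replicates 1 and 2. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name bcl2fastq, HISAT2 and the mm10 build. Their versions, the counting tool, the gene annotation and any use of strand are not given in the sources used here.

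The deposited values came as 2 tables. Both replicate 1 libraries stood in a table of FPKM values made by the authors (fragments scaled to gene length and to the mapped total), with 30780 genes. Both replicate 2 libraries stood in a deposited table of RPKM values (reads scaled in the same way), with 18117 genes. The tables use different gene models and were normalised separately, so the main test compares values only within a table. The fits without the block or without a library, and the factor levels set side by side at the close, cross the tables. Each column was tied to its sample through the label that names the table and through its name.

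The tables were joined by gene symbol or synonym with overlapping positions. This gave 17298 genes, of which 544 were matched by a synonym. A further 35 genes with the same symbol at another position were left out, and 819 genes of the replicate 2 table found no partner. Of the gene identifiers in the replicate 1 table, 99.8% were found in the GENCODE mouse annotation of the same build used here, and 93.2% had identical positions. Reads behind the units were recovered from the low values, where the value times the gene's length gives whole reads. The totals were 16867859 reads for SKO+Flag replicate 1, 16477220 for SKO+Glis1 replicate 1, 19026569 for SKO+Flag replicate 2 and 18404400 for SKO+Glis1 replicate 2. With a tolerance of 0.01 reads, 88.1% of the joined genes were whole in both replicate 1 libraries and 21.1% in both replicate 2 libraries. Reads of single genes in replicate 2 are therefore estimates, made with gene lengths that may not be those of the deposited table.

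Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(value + 1), for genes with a mean value of at least 1 over the 4 libraries. The replicate number, which is also the deposited table, was a block. P-values are two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. The fit had 1 residual degree of freedom and 5.33 prior degrees of freedom borrowed across genes. Each SE given with a fold change is limma's moderated SE, which rests mostly on the spread of other genes. It is not the spread between the 2 pairs of libraries for that gene, and can be smaller. The labels place same-numbered libraries in 1 table, and their deviations from the group means had a correlation of 0.944 across genes. A shared table would give a high correlation by itself, so this value does not show that the cultures were paired. Nothing in the labels says that the replicates came from separate cultures. The p-values of single genes then measure only the spread between these libraries, which may be technical. The squared difference between the 2 log2 ratios of a gene was, at the median over 11050 genes with at least 50 estimated reads in each library, 3.84 times that of counting noise.

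There were 26 gene lists fixed before the data were examined. Of these, 21 had at least 5 tested members and were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. At the preset correlation, the error in camera is the spread across the tested genes and not that across libraries. Its p-values, however small, are therefore no evidence across replicates. Camera with an estimated correlation and fry were run beside the preset one. With the correlation estimated, camera has only the 1 residual degree of freedom. It could then hardly pass any list, and cannot decide whether correlation between genes removes a call. Biological process terms that the deposited annotation gives for the genes were tested the same way, over 1053 terms of 15 to 300 tested genes. The genes named were fixed by a rule. It took Glis1, Glis2, Glis3, Pou5f1, Sox2, Klf4 and Myc; the 6 largest increases and 6 largest decreases among called genes with the same direction in both replicates, without unnamed gene models; the 3 members with the smallest p of each primary list; and the 2 of each other list. Some genes the rule selects are not reported here, and none were put in their place. Any further gene the text names was chosen after its values were seen.

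The test was checked on simulated data for SKO+Glis1 against SKO+Flag with 12046 genes, of which 200 were changed, at a dispersion of 0.01. It recovered 40 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold. It called 42 unchanged genes, and 36 of these were among the 337 unchanged genes with under 50 reads. Wrong calls thus made up more of the calls than the threshold of 0.05 allows. Voom on estimated reads called 13 unchanged genes. The simulation held far fewer changed genes than were called in the real data. Its dispersion was set and not estimated from these libraries, so the rates of recovered and wrong calls may not hold for them. In the real data, 339 tested genes had under 50 estimated reads, of which 103 were called. Of unchanged lists of 20 genes, 9 of 200 had a camera p under 0.05. The simulated genes varied independently of each other, so that this does not check lists whose genes vary together. The alternatives were no replicate block, other pseudocounts, filters and scalings, eBayes without trend, and leaving out each replicate number and each library. After the data were seen, voom on estimated reads, a correction for GC content and length, and a filter on estimated reads were added. Figures were drawn with matplotlib 3.10.9, and tables were read with Python 3.11.15 and pandas 2.3.3. Genes present in a single table were not tested. Of list members with means too low to test, the directions are counted without a test, and equal reads in a pair count as neither higher nor lower.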

Results

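The transcriptomes of reprogramming mouse embryonic fibroblasts were compared on day 8 after infection with SKO plus Glis1 (2 libraries) or SKO plus a Flag control (2 libraries). The series title names glycolysis and the promoters of pluripotency genes as the subject, so the comparison asks which genes differ when Glis1 is added. Between 16477220 and 19026569 reads stood behind the units of each library. Intervals on reads given here cover counting error only.

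Glis1, the added factor (ENSMUSG00000034762, chromosome 4, 107434591 to 107635061, plus strand, mm10), was not higher in the libraries labelled SKO+Glis1. In replicate 1 it stood at 0.407 FPKM (25 reads) in the library labelled SKO+Flag and 0.400 FPKM (24 reads) in the library labelled SKO+Glis1. The ratio was 0.983, with an exact binomial 95% interval of 0.537 to 1.79. In replicate 2 it stood at 1.21 RPKM with SKO+Flag and 0.617 RPKM with SKO+Glis1. The smallest whole reads with that ratio are 67 and 33, which gives a ratio of 0.509 (exact 95% interval 0.325 to 0.784). Its mean lay under the filter, so that it was not tested with the other genes. The values therefore do not show the added Glis1 that the label names. Every direction below is that of the libraries labelled SKO+Glis1 relative to those labelled SKO+Flag.

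The shared factors were abundant in all 4 libraries. Pou5f1 stood at 203 and 233 FPKM in replicate 1, and at 1204 and 1246 RPKM in replicate 2, with SKO+Flag named first. Sox2 stood at 83.8 and 142 FPKM, and at 751 and 804 RPKM. Klf4 stood at 299 and 405 FPKM, and at 918 and 983 RPKM. None of these passed the test, with adjusted p = 0.278 for Pou5f1, 0.0637 for Sox2 and 0.0876 for Klf4 in limma. Sox2 and Klf4 passed under other settings, at an adjusted p = 2.62e-03 and 8.47e-03 with voom, so that a difference in these factors is not excluded. Reads of a vector and of the endogenous gene cannot be separated in these values. Glis2, a relative of Glis1, had a log2 fold change of -0.18 (adjusted p = 0.0886) and Glis3 of 0.01 (adjusted p = 0.962). Glis2 passed under other settings, at an adjusted p = 0.0403 with voom. Myc, a growth regulator outside the SKO set, rose by 0.73 ± 0.06 (SE, log2 scale, adjusted p = 5.17e-04).

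**Figure D1:**
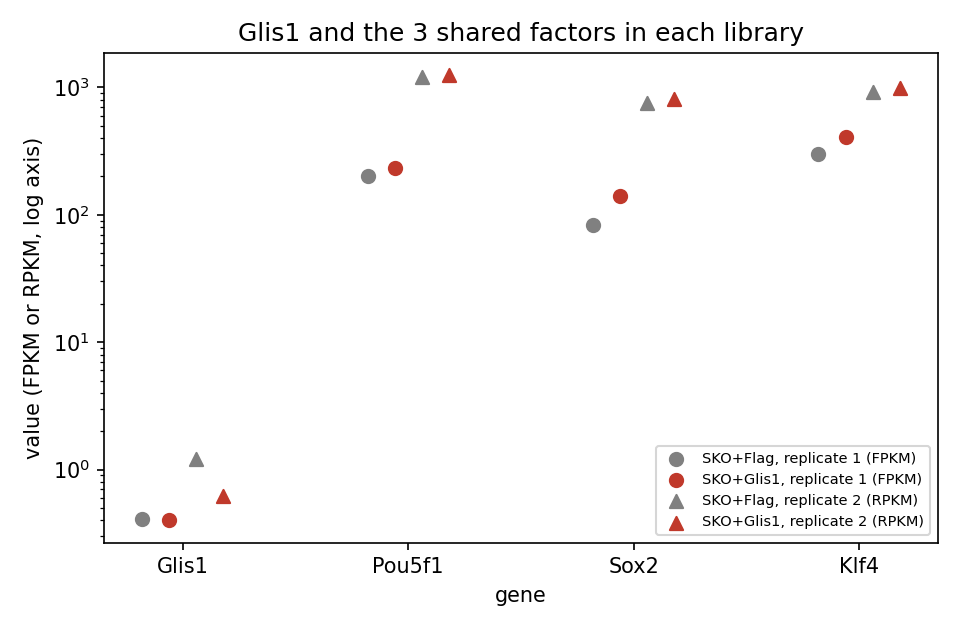
Values of Glis1, Pou5f1, Sox2 and Klf4 in each of the 4 libraries, as FPKM for replicate 1 (circles) and RPKM for replicate 2 (triangles) on a log axis, grey for SKO+Flag and red for SKO+Glis1. Glis1 lies between 0.400 and 1.21, while the lowest value of the shared factors is 83.8 for Sox2.

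Across all genes, the largest increases in the libraries labelled SKO+Glis1 were those of Trpv5, a calcium channel, Il11, a cytokine, Krt19, an epithelial keratin, Pcp4l1, Tub and Col9a2, a cartilage collagen chain. Trpv5 stood at 0.128 and 35.3 FPKM in replicate 1 and at 0.162 and 37.4 RPKM in replicate 2, a log2 fold change of 5.03 ± 0.09 (SE, n = 2 per group). The log2 fold changes of the others were 3.86 for Il11, 3.83 for Krt19, 3.82 for Pcp4l1, 3.77 for Tub and 3.70 for Col9a2. The largest decreases were those of the milk protein gene Csn1s1 (-3.08), the embryonic globin Hbb-y (-2.85), the secreted Wnt modulator Sfrp4 (-2.64), the matrix proteoglycan Fmod (-2.62), the BMP antagonist Sostdc1 (-2.56) and Fam180a (-2.43). Of 12048 genes tested with limma, 2565 were higher and 1994 lower, and 310 and 296 of these by at least 2-fold. All 4559 called genes had the same sign in both tables. With 1 residual degree of freedom, a gene with opposite signs could not reach the threshold, so this agreement follows from the test. Without a test, 235 genes were at least 2-fold higher and 199 at least 2-fold lower in both tables.

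The log2 ratios of the 2 pairs of libraries had a Pearson r of 0.865 and a Spearman rho of 0.814 across the 12048 genes, and 81.5% of genes had the same sign. Genes are not independent replicates, and this is no test across samples. Without the block, the values of the FPKM and RPKM tables are mixed within a group, and limma called 0 genes, with 888 at an unadjusted p under 0.05. Each fit that left out 1 library also called 0 genes.

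**Figure D2:**
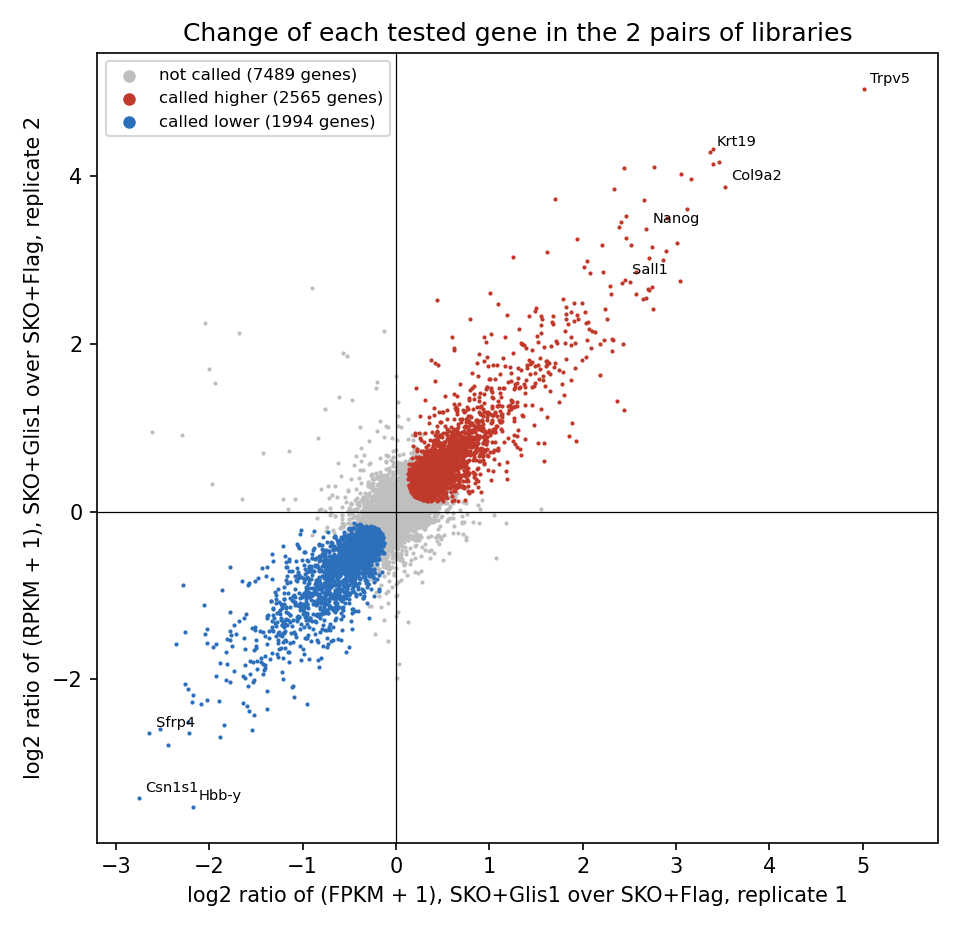
Log2 ratio of SKO+Glis1 over SKO+Flag for each of 12048 tested genes, replicate 1 on the horizontal axis (FPKM + 1) and replicate 2 on the vertical axis (RPKM + 1), coloured by the limma call. Called genes, 2565 higher and 1994 lower, lie in the quadrants where both pairs have the same sign, as a call requires. Trpv5 lies farthest from the origin.

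Genes of glycolysis rose together in the libraries labelled SKO+Glis1. Of 23 tested members, 19 rose, none fell and 4 did not pass, or 19 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.62. The glucose transporters Slc2a3 and Slc2a1 rose by 1.49 ± 0.06 and 1.40 ± 0.07 (SE). Pfkp, the platelet form of phosphofructokinase, rose by 1.19 ± 0.06, and the lactate transporter Slc16a3 by 1.51. Gpi1, Hk1, Pfkfb4 and Pfkm were not called, at -0.07, -0.12, -0.04 and -0.21. The enolase Eno1 was read in replicate 1 alone, at 104 and 172 FPKM. The list passed camera with an adjusted p = 1.02e-05, and had an adjusted p = 0.690 with an estimated correlation.

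Genes of the hypoxia response rose as well. Of 14 tested members, 10 rose and 0 fell, with the same counts when adjusted over the list alone. Adm, a vasodilator peptide, rose by 2.33 ± 0.08 and the mTOR inhibitor Ddit4 by 1.98 ± 0.08 (SE, log2 scale). Camera gave the hypoxia list an adjusted p = 9.97e-04, against an adjusted p = 0.690 with an estimated correlation.

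Of the pluripotency genes, 14 were tested, 8 rose and 0 fell, or 9 and 0 when adjusted over the list alone. Nanog, a core pluripotency factor, stood at 0.608 and 9.28 FPKM in replicate 1 and at 0.563 and 15.1 RPKM in replicate 2. Its log2 fold change was 3.02 ± 0.17 (moderated SE), from log2 ratios of 2.68 in replicate 1 and 3.37 in replicate 2. Sall1 rose by 2.61 ± 0.09 and the RNA-binding protein gene L1td1 by 1.20 ± 0.07. Mycn, Zfp296 and Tdh rose by 1.82, 1.84 and 1.63. Fgf4, Tbx3 and Tfcp2l1 were not called, at 0.03, -0.05 and -0.10. Another 18 members were not tested, 12 of them present in both tables with a mean under 1, where 6 were higher and 2 lower in both replicates. Among these, Nr5a2 stood at 0.0603 and 0.700 FPKM and at 0.0409 and 0.930 RPKM. Zfp42, 1 of the 2 that were lower, stood at 0.851 and 0.548 FPKM and at 0.875 and 0.543 RPKM. Of the members not in both tables, Dppa3 was listed at 0 in both replicate 1 libraries. The list passed camera with an adjusted p = 7.64e-04, and had an adjusted p = 0.690 with an estimated correlation.

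Of the epithelial genes, 13 were tested, 8 rose and 0 fell, with the same counts when adjusted over the list alone. Krt19 led the list, Krt8 rose by 0.77 ± 0.09 and the adhesion molecule gene Epcam by 0.61 ± 0.07 (SE, log2 scale). Cdh1, the gene of E-cadherin, was not called (0.09, adjusted p = 0.703). Of 12 members with a mean too low to test, 6 were higher and 3 lower in both replicates. In camera the epithelial list had an adjusted p = 2.57e-03, and had an adjusted p = 0.690 with an estimated correlation.

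Fibroblast genes were lower on balance. Of 30 tested members, 15 fell and 7 rose, or 16 and 7 when adjusted over the list alone, and the median log2 fold change was -0.42. The matrix gene Postn fell by 1.29 ± 0.06 and the collagen gene Col6a2 by 1.16 ± 0.06 (SE). The members that rose were Cdh2 (1.25 ± 0.08), Fosl1, Pdgfra, S100a4, Snai1, Twist1 and Twist2, of which Snai1, Twist1 and Twist2 encode transcription factors of the mesenchymal state. The list passed camera downward with an adjusted p = 5.70e-04, and had an adjusted p = 0.690 with an estimated correlation.

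Cell cycle genes rose together. Of 26 tested members, 23 rose and 0 fell, or 24 and 0 when adjusted over the list alone, with a median of 0.63. Ccne1, a cyclin of S phase entry, rose by 1.64 ± 0.08, the topoisomerase Top2a by 1.16 ± 0.06 and the mitotic cyclin Ccnb1 by 1.03 ± 0.07 (SE, log2 scale). For the cell cycle list camera gave an adjusted p = 8.44e-09, and had an adjusted p = 0.690 with an estimated correlation.

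Interferon response genes fell together. Of 16 tested members, 13 fell and 1 rose, or 14 and 1 when adjusted over the list alone, with medians of -0.42 in replicate 1 and -0.67 in replicate 2. Ifit1 fell by 1.36 ± 0.11 and Ifit3 by 1.11 ± 0.14 (SE, log2 scale), both antiviral genes, and Ddx58 was the member that rose, by 0.35. Of 4 interferon members with means too low to test, 1 was higher and 2 lower in both replicates. Of 4 tested macrophage genes, Lyz2 and Itgam fell too, at -1.58 and -0.81, while Cd14 and Cd68 were not called. Lyz2 stood at -2.28 in replicate 1 and -0.88 in replicate 2, and Itgam at -0.44 and -1.18. The list passed camera downward with an adjusted p = 3.99e-05, and had an adjusted p = 0.690 with an estimated correlation.

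**Figure D3:**
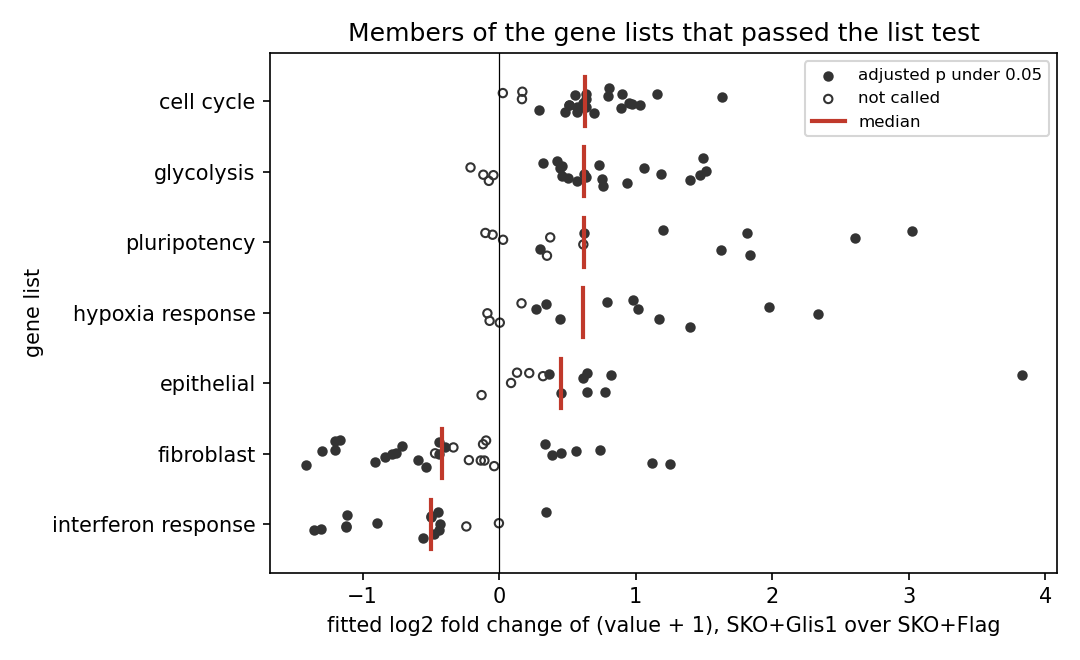
Fitted log2 fold changes of (value + 1), SKO+Glis1 over SKO+Flag, for the members of the 7 lists that passed camera, 1 point per gene, filled where the gene was called, with the list median as a red bar. All cell cycle members lie above 0, whereas the fibroblast list has 15 called members below and 7 above 0.

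Lists of metabolism and chromatin did not pass. Of 31 oxidative phosphorylation genes, 2 rose and 1 fell, or 0 and 0 when adjusted over the list alone (camera adjusted p = 0.760). Ndufa1 fell by 0.24 (log2 scale), a call that ended under other settings. Of 21 genes of acetyl-CoA supply and the TCA cycle, 5 rose and 1 fell, or 4 and 1 when adjusted over the list alone (adjusted p = 0.331), and the members with the smallest p were Idh2 (0.55) and Aco1 (0.43). Of 23 genes of histone acetylation, 6 rose and 2 fell, in both counts (adjusted p = 0.426), and those with the smallest p were the deacetylases Hdac6 (1.23) and Hdac1 (0.57 ± 0.06). Transcripts of the mitochondrial genome were read in replicate 1 alone, mt-Co1 at 6074 and 6362 FPKM and mt-Nd1 at 2859 and 2583 FPKM.

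Lists of stress and signalling held members that went both ways. Of 20 p53 targets, 7 rose and 3 fell, in both counts (adjusted p = 0.438). Sesn2 rose by 0.95 and Btg2 by 0.49, and the death receptor Fas fell by 0.89 (log2 scale). Of 17 genes of senescence and its secreted factors, 6 rose and 7 fell, in both counts (adjusted p = 0.843), with Igfbp5 at 2.59. Their median was -0.10 and their mean 0.22. Of 10 genes of the Wnt pathway, 3 rose and 4 fell, or 3 and 5 when adjusted over the list alone (adjusted p = 0.439). The ligand Wnt5a fell by 0.86 and the Wnt inhibitor Notum rose by 1.80. Another 10 members were not tested, and of the 9 with values in both replicates 7 were higher and 2 lower in both. Wnt3 stood at 0.0385 and 2.31 FPKM and at 0.0337 and 1.26 RPKM, and Sp5, a target of the pathway, at 0.0282 and 0.520 FPKM and at 0.125 and 1.63 RPKM. Of 5 Hedgehog pathway genes, 1 rose and 2 fell, in both counts (adjusted p = 0.331), with Ptch1 at 0.96 and Smo at -0.52. Of 5 members with means too low to test, 4 were higher and 0 lower in both replicates. Of 13 immediate early genes, 7 rose and 2 fell, or 7 and 3 when adjusted over the list alone (adjusted p = 0.438), with Ier3 at 1.38 and Jun at 0.85. Another 2 had means too low to test, with 0 higher and 2 lower in both replicates.

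Markers of other cell types moved apart. Of 5 keratinocyte genes, 3 rose and 0 fell, in both counts (adjusted p = 0.0774), with Krt6a at 3.09 and Sfn at 2.09. Of 7 cartilage and bone genes, 2 rose and 4 fell, in both counts (adjusted p = 0.106), with Col2a1 at -1.34 and Bglap at -1.79 from a mean of 29.5 estimated reads. Of 6 neural genes, 3 rose and 2 fell, or 4 and 2 when adjusted over the list alone (adjusted p = 0.431), with Nes at 1.65 and Map2 at 1.21. Of 5 endothelial genes, 2 rose and 1 fell, in both counts (adjusted p = 0.673), with Esam at 1.29 and Kdr at 1.09. Of 7 genes of extraembryonic endoderm, 1 rose and 3 fell, in both counts (adjusted p = 0.357), with Dab2 at -1.06 and Fgfr2 at 0.78. Of 7 contractile and muscle genes, 1 rose and 1 fell, or 2 and 2 when adjusted over the list alone (adjusted p = 0.592), with Cnn1 at 1.05 and Acta2 at -0.27, a call that ended under other settings. Lists with too few tested members for camera gave Tead4 at 0.41 and Gata3 at 0.06, not called, of 2 trophoblast genes, and Lpl at -1.65 and Cebpa at -0.46, not called, of 2 adipocyte genes. Adjusted over the list alone, 1 trophoblast gene was higher and 2 adipocyte genes were lower. Of 4 macrophage genes 0 rose and 2 fell, in both counts, and the calls of Lyz2 and Itgam ended under other settings. No member of the 2-cell stage list was tested. Of members with means too low to test, 6 of 9 macrophage genes were lower and 0 higher in both replicates. The keratinocyte list had 3 higher and 2 lower of 6, the neural list 2 and 3 of 8, the endothelial list 1 and 3 of 6, the cartilage and bone list 1 and 1 of 5, the contractile list 1 and 1 of 7, and the trophoblast list 2 and 0 of 6.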

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

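All tests that weigh an explanation in this part, with their limits, and the rule that picked the genes read in a single table, were chosen after the results had been seen.

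Among genes in a single table, which the comparison leaves out, those of at least 5 FPKM or RPKM and at least 4-fold over the control library were looked for, with a span of at least 1000 bases. The span limit was set after the values had been seen, and left out 8 shorter genes of the replicate 1 table and 6 of the replicate 2 table. There were 3 such genes, all in replicate 1, with no replicate check. The unnamed transcript 2310043P16Rik (chromosome 7, 34389732 to 34393612, mm10) stood at 2.66 FPKM with SKO+Flag and 40.1 FPKM with SKO+Glis1. Gm12764, which overlaps it on the same strand (34388665 to 34394779), stood at 0.288 and 6.39 FPKM, and reads of this pair cannot be told apart with certainty. The protein-coding gene 1520401A03Rik (chromosome 17, 23704488 to 23722783, mm10) stood at 0.0577 and 7.59 FPKM.

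Glis1 reads were not higher in the libraries labelled SKO+Glis1. Counting error is argued against, since the higher of the 2 upper exact 95% bounds of the ratio to SKO+Flag was 1.79. It stays open whether vector Glis1 may have been transcribed but not counted under the mouse gene, or was not expressed on day 8. The ratio was 0.983 in replicate 1 and 0.509 in replicate 2 (exact 95% interval 0.325 to 0.784), and neither of these accounts by itself for the lower reads of replicate 2. An exchange of labels between the groups stays open too: the highest Glis1 level of a SKO+Flag library was 0.485% of its lowest shared factor, which would argue against it only if vector reads were counted under the mouse gene.

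Fibroblast genes were lower and epithelial and pluripotency genes higher. A lower share of fibroblasts stays open as a cause. Of 45 tested members of the lists of 9 other cell types, 14 were called lower and 13 higher. This cannot decide the question, since the shares of other cell types may have changed too. Fibroblasts also express some of those that fell, such as Sparc, Lamc1, Dab2 and Acta2. Within the fibroblast list itself, 15 of 30 tested members fell and 7 rose. Bias from GC content or gene length is argued against, since the fibroblast list kept an adjusted p = 6.94e-04 after a correction for both. This p is from camera with the preset correlation. A change within cells, from the factors the labels name, may contribute and was not tested.

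Interferon genes were lower. Bias from GC content or length is argued against, since the list had an adjusted p = 3.68e-05 after the correction, in camera with the preset correlation. Macrophage RNA in the libraries labelled SKO+Flag could contribute and stays open, since 2 of the 4 tested macrophage markers, Cd14 and Cd68, lay above the interferon median by over 2 standard errors while Lyz2 and Itgam fell. Of 9 macrophage genes with means too low to test, 6 were lower and 0 higher in both replicates: Tyrobp stood at 0.978 and 0.0910 FPKM and at 0.371 and 0 RPKM, with SKO+Flag first, C1qa at 1.48 and 0.350 FPKM and at 0.291 and 0.251 RPKM, while C1qb was lower in replicate 1 alone. The interferon median was lower in replicate 2 (-0.67) than in replicate 1 (-0.42).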

How the results depend on the processing

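Voom on estimated reads, the correction for GC content and length, and the filter on estimated reads were chosen after the data were seen. Without the block on replicate number, and without each library in turn (range 0 to 0), limma called 0 genes higher and 0 lower, with 888 genes at an unadjusted p under 0.05 without the block. These fits mix FPKM and RPKM values, or leave a group with a single library that is assumed to vary like the rest. In such fits the log2 fold change of Hdac1 ran from -0.21 to 1.34. It was reversed without SKO+Flag replicate 1 (-0.17) and without SKO+Glis1 replicate 2 (-0.21), which follows from the difference between the tables. All other settings gave counts within 1.5 times those reported, from 1898 to 3203 higher and from 1588 to 2532 lower, and no gene called there had the opposite direction. Voom called 4429 of the reported genes, the GC and length correction 4380, quantile normalization 4287, and 3967 were also called with the median log2 ratio of both tables set to 0. Fewer were called with a pseudocount of 5 (3855), eBayes without trend (3752), a mean of at least 5 (3565) and no filter (3148). The share of calls that were higher ran from 47.5% to 58.8%. The 7 lists kept their calls under all settings of camera with the preset correlation that were run. With an estimated correlation, each of the 7 had an adjusted p = 0.690 in camera, as did lists that had not passed, such as p53 targets. The correlations estimated were 0.40 for glycolysis, 0.35 for cell cycle, 0.27 for hypoxia and 0.75 for interferon, against the preset 0.01. They were 0.12 for pluripotency, -0.02 for fibroblast and -0.08 for epithelial. The test with an estimated correlation has 1 residual degree of freedom and cannot decide whether correlation between genes removes the calls. With fry, the adjusted p was 0.0939 for glycolysis, pluripotency, cell cycle and hypoxia, 0.0826 for epithelial and fibroblast, and 0.194 for interferon. With fry in either direction it was 0.0648 for glycolysis, pluripotency, epithelial, cell cycle and hypoxia, 0.103 for interferon, and 0.0411 for fibroblast, the 1 of these 7 that stayed under the threshold. Calls were also gained. In either direction, fry gave 0.0411 for senescence, contractile and muscle, neural, and cartilage and bone. With camera, the keratinocyte list passed with voom (0.0256), without the block (0.00425) and without 3 of the 4 libraries in turn (9.46e-07 to 0.0484), and the cartilage and bone list without the block (0.0462) and without 2 of the libraries (0.0102 and 0.0484). Sox2 passed with voom (0.00262), quantile normalization (0.0485), a mean of at least 5 (0.0283) and at least 50 estimated reads (0.0421), Klf4 with voom (0.00847), and Glis2 with voom (0.0403) and quantile normalization (0.0459), all as adjusted p. These estimates rest on 1 residual degree of freedom. The Pearson r between the pairs was 0.909 and the share of genes with the same sign 82.6% at a mean of at least 5, and 0.824 and 74.8% with no filter. The r was 0.818 with a pseudocount of 0.1, 0.883 with a pseudocount of 5, and 0.900 with at least 50 estimated reads; the cause was not tested. Genes with under 50 reads made up 36 of the 42 wrong calls in simulated data, and the cause was not tested.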

Other observations

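All tests in this part were chosen after the gene results had been seen.

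Of 1053 annotated processes, 21 passed camera upward and 19 downward, and only some are given here. DNA replication (44 of 90 tested genes higher, 2 lower, adjusted p = 7.08e-05) and chromosome segregation (45 of 76 higher, 3 lower, adjusted p = 8.84e-05) rose with the cell cycle list. RNA splicing, a process outside the fixed lists, had 78 of 180 genes higher and 4 lower (adjusted p = 1.91e-04), and DNA repair 71 of 214 higher and 10 lower (adjusted p = 3.51e-03). Collagen fibril organization had 20 of 34 genes lower and 1 higher (adjusted p = 7.08e-05), and biomineral tissue development 11 of 15 lower and 1 higher (adjusted p = 4.94e-03). The response to interferon-beta had 17 of 28 genes lower and 3 higher (adjusted p = 5.94e-03). Cilium assembly had 33 of 105 genes higher and 6 lower (adjusted p = 0.0396). Downward terms outside the fixed lists passed as well. The adenylate cyclase-activating G-protein coupled receptor pathway had 11 of 25 genes lower and 0 higher (adjusted p = 1.84e-03). The neuropeptide signaling pathway had 11 of 24 lower and 1 higher (adjusted p = 6.64e-03). These terms share genes, and camera used the preset correlation. They also hold genes of the fixed lists, such as Top2a and Ifit1, so that they are no separate support for those lists. The deposited annotation was used unchecked. It places Pcp4l1 under DNA replication and DNA repair, and Skida1 under the response to interferon-beta.

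The shared factors stood higher in the replicate 2 table than in the replicate 1 table, by 5.94-fold for Pou5f1, 8.96-fold for Sox2 and 3.07-fold for Klf4 in the SKO+Flag libraries, against a median of 1.40-fold over all tested genes. The tables were normalised separately and use different gene models, so these are values and no comparison of the cultures.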
